A study of Mus musculus and Homo sapiens with 30 samples.

How the data were processed

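The series held 30 samples: 18 RNA-seq libraries of NMuMG cells and 12 ATAC-seq samples of NMuMG and HK-2 cells, each with an empty vector or a short hairpin against PBRM1. Per the labels each group was a biological triplicate, so errors and tests describe variation between such replicates. The labels do not say whether knockdown cells were made more than once. RNA values were gene counts, deposited by the authors as a table of 53715 genes made from aligned reads; the submitters' processing notes list Trimmomatic, STAR, HISAT2, Bowtie2, HTSeq, bedtools, DESeq2, edgeR, SICER and HOMER without versions or settings, and mm10 and hg19 as genome builds. ATAC values were the authors' deposited lists of regions with increased or decreased accessibility. For HK-2 the increased list carried a column headed as a SICER fold change. The decreased list carried one headed Peak Score, which was assumed to be a fold change because both headers name a 1.5-fold threshold and values in both lists were at least 1.5. NMuMG lists carried no fold change, and all 4 lists carried HOMER's distance from the region centre to the nearest transcription start, in bp as deposited. The headers of both HK-2 lists name hg38 where the notes name hg19. Reads and peak signals were not among the files, so accessibility could not be tested again and each list stands as deposited.

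Libraries held 29149000 to 44457000 counts, with a median of 33223900. Symbols were found for 53620 gene identifiers (99.8%), and gene positions came from a mm10 annotation. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and region lists in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Genes passed filterByExpr at its defaults (15169 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean for each of the 6 groups and 12 residual degrees of freedom was fitted to all 18 libraries. The contrasts tested were 10: knockdown against vector in each condition and on average, each stress against no stress in vector and in knockdown cells, and the interaction of knockdown with each stress. P values were adjusted by Benjamini-Hochberg within each contrast, and genes were called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic, and CPM values are scaled by TMM. Changes were simulated in 100 genes at each fold, all of at least 5 mean CPM, so recovery of genes with lower counts was not tested. Of 14928 genes run, the unstressed knockdown comparison recovered 90 of these at 1.5-fold and 96 at 2-fold, and called 8 unchanged genes. The H2O2 comparison recovered 84 and 97, and the interaction with H2O2 65 and 94.

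Comparisons, gene lists, tests and alternatives were chosen before the data were examined, unless stated. The 24 gene lists and 5 lists of markers of other cell types were written from general knowledge. The 27 lists with at least 3 tested members were tested in the 10 contrasts with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with p values adjusted over all 270 tests. Lists were also tested with a correlation estimated for each list and with fry, which tests whether the genes of a list move one way on balance. Luminal and fibroblast marker lists had fewer tested members. Named genes follow a rule: Pbrm1, the 6 largest rises and 6 largest falls of each contrast among called genes of at least 5 mean CPM in a group and without overlap between groups, and up to 4 members of smallest adjusted p in each list. Predicted and clone-named genes were left out of the rises and falls, and some members of lists are not reported. Of each region list the 3 regions of highest fold or, without folds, of greatest width were named. Of the regions nearest to named genes only some are given, so their directions do not stand for all. On a sex chromosome 1 HK-2 region is not described.

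The change of RNA and accessibility was compared by two-sided Fisher exact tests over genes that were nearest to regions of 1 direction alone, and the 2 cell lines were compared over genes of the same symbol. Distances of 5000 bp and HOMER's promoter class were alternatives. For RNA the alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter or a minimum of 5 mean CPM, only the groups compared, the replicate number as a block, a 2-fold threshold, and leaving out each library in turn. Added after the data were seen were leaving out 5 libraries (PBKD 1, vector_H2O2 2, PBKD_H2O2 3, vector_low_glucose 1 and PBKD_low_glucose 1), leaving out each library in turn for the overlap of both stresses, 2 surrogate variables from svaseq, leaving out genes that set vector_H2O2 replicate 3 apart, the chromosome tests, and a test of HK-2 regions in windows with a high share near transcription starts. The 5 libraries were the most distant of each group in which one lay more than 1.2 times the median distance from its group; vector_H2O2 3 (1.32 times) and PBKD 2 (1.31 times) also lay beyond 1.2 and were kept. Whether replicate numbers pair the libraries was checked by correlating their deviations from the group means. In low glucose the vector and knockdown pairs correlated at 0.63, 0.28 and 0.53, each over 0.1. The numbers were taken as pairs in that comparison from the data alone, and elsewhere as numbers only. Its main fit stayed unpaired, and the pairing entered only as the replicate block, with 4978 genes called against 5145. No reference genome was given, so neither base composition nor reads from near-identical copies were checked.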

Results

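RNA was sequenced from NMuMG, a mouse mammary gland epithelial cell line, carrying either an empty vector or a lentiviral short hairpin against PBRM1, the subunit of the PBAF chromatin remodelling complex that holds several bromodomains. Knockdown libraries carried the label PBKD. Cells of both kinds were left unstressed, given 200 µM H2O2 for 2 hours or kept without glucose for 6 hours, which made 6 groups of 3 libraries. Libraries held 29149000 to 44457000 gene counts, and 15169 of 53715 genes passed the filter on low counts. Mitochondrially encoded genes took 3.20% to 4.05% of counts and the 10 most abundant genes 5.81% to 6.49%. The first principal component held 43.6% of the variance between libraries and the second 12.3%. Chromatin accessibility had been measured by ATAC-seq in NMuMG and in HK-2, a human kidney proximal tubule cell line, in 12 samples, and was analysed here as the 4 deposited lists of regions that gained or lost accessibility. Errors of log2 fold changes are standard errors from edgeR with n = 3 libraries per group, and CPM values are mean ± SD over 3 libraries.

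The target gene was lower in each of the 9 knockdown libraries than in any vector library. Pbrm1 (ENSMUSG00000042323, mm10 chromosome 14, 31019138 to 31121592) stood at 133 ± 4.94 CPM in unstressed vector cells and at 64.2 ± 2.70 CPM in unstressed knockdown cells, a log2 fold change of -1.06 ± 0.05. With H2O2 the levels were 139 ± 7.72 and 70.0 ± 3.97 CPM, and in low glucose 148 ± 2.96 and 67.7 ± 1.33 CPM. The change was -0.98 with H2O2 and -1.13 in low glucose (edgeR quasi-likelihood test, both past a Benjamini-Hochberg adjusted p of 0.05). In vector cells Pbrm1 itself had a change of 0.05 ± 0.05 with H2O2 and 0.15 ± 0.05 in low glucose, which missed the threshold at adjusted p values of 0.54 and 0.052 by the edgeR test.

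**Figure D1:**
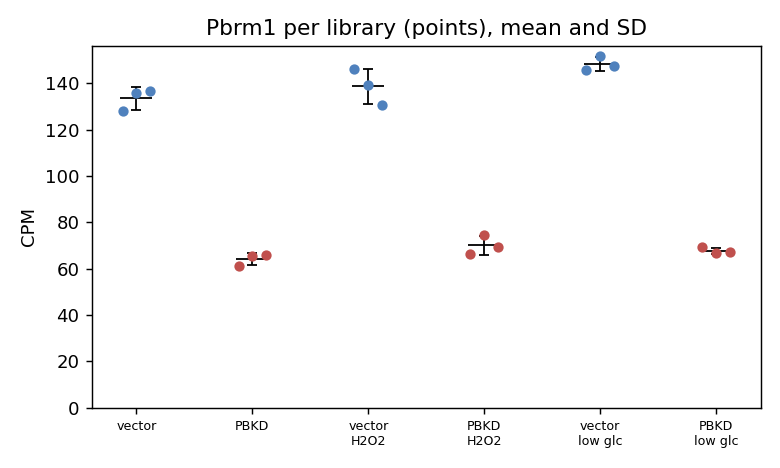
Pbrm1 in CPM (vertical axis) in the 6 groups (horizontal axis). Points are single libraries, black marks the mean and SD of 3 libraries, blue is vector and red is knockdown; the highest knockdown library, at 74.3 CPM, lies under the lowest vector library, at 128 CPM.

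The comparison of unstressed knockdown and vector cells asks which genes depend on PBRM1 without stress. Here and below, rises and falls are ranked among called genes of at least 5 mean CPM in a group and without overlap between groups. Predicted and clone-named genes are left out of that ranking, and genes named from lists can lie outside it. The largest rises were in Cacna1e, a voltage-gated calcium channel subunit, which went from 0.738 ± 0.165 to 5.80 ± 0.949 CPM (log2 2.97 ± 0.19), Sult1a1, a phenol sulfotransferase (2.43 ± 0.46), the membrane trafficking protein gene Mal2 (2.19 ± 0.15), Cttnbp2 (2.16 ± 0.17), the interferon-inducible GTPase gene Gbp4 (2.10 ± 0.27) and the glucuronosyltransferase gene Ugt2b36 (2.07 ± 0.33). The largest falls were in Zdhhc15, a palmitoyltransferase, from 12.4 ± 0.303 to 0.180 ± 0.024 CPM (-6.06 ± 0.21), Ripor2 (-3.87 ± 0.33), Armcx4 (-3.85 ± 0.22), Pogk (-3.83 ± 0.17) and the cell junction scaffold gene Mpdz (-3.72 ± 0.13). By the edgeR quasi-likelihood test 2370 genes rose and 2424 fell at an adjusted p under 0.05, of which 354 and 544 changed at least 2-fold. Uqcrc1 (-3.70 ± 1.12) was also called, but its value came to -0.58 and lost its call without vector replicate 1, and the call also ended without PBKD replicate 2 or 3.

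Of 21 tested NF-kB and inflammatory genes 11 rose and 1 fell in unstressed knockdown cells (12 and 2 adjusted over the list alone), among them the neutrophil chemokines Cxcl1 (1.45 ± 0.12) and Cxcl5 (1.30 ± 0.21), the adhesion molecule Vcam1 (1.43 ± 0.18) and the acute-phase gene Saa3 (2.33 ± 0.41). The camera test of that list gave an adjusted p of 0.0214, and adjusted p = 0.695 with an estimated correlation. Of 14 mesenchymal genes 9 fell and 0 rose (9 and 0 adjusted over the list alone), among them the collagen gene Col5a1 (-2.72 ± 0.17), the transcription factor Twist2 (-3.27 ± 0.43), the fibronectin receptor subunit Itga5 (-0.72 ± 0.07) and S100a4 (-1.21 ± 0.17). Camera gave this list 0.000493, and adjusted p = 0.0981 with an estimated correlation. Of 21 basement membrane and integrin genes 10 fell and 1 rose (12 and 2 adjusted over the list alone), with the laminin chains Lamb3 (-1.14 ± 0.07) and Lamc1 (-0.38 ± 0.05) and the matrix glycoprotein Thbs1 (-0.81 ± 0.12) among those that fell. The camera adjusted p was 0.0131, and adjusted p = 0.695 with an estimated correlation. Of 15 epithelial genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), led by the keratin Krt7 (-1.84 ± 0.13), the tight junction gene Marveld2 (-0.67 ± 0.12) and the desmosome gene Dsp (-0.57 ± 0.11), and that list missed the camera threshold at an adjusted p of 0.274. Fibroblast markers were low in both kinds of cell, with Pdgfra at 3.13 CPM in vector and 1.04 CPM in knockdown cells (-1.58 ± 0.17) and Col6a3 at 0.548 and 0.0670 CPM (-2.87 ± 0.56), so they fell together with the mesenchymal genes.

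Of 23 chaperones and targets of ATF6 or XBP1 in the endoplasmic reticulum 16 fell and 0 rose (16 and 1 adjusted over the list alone), including Xbp1 itself (-0.44 ± 0.05), Canx (-0.25 ± 0.04), Manf (-0.78 ± 0.13) and Hyou1 (-0.41 ± 0.07). By camera the adjusted p was 0.000159, and adjusted p = 0.383 with an estimated correlation. ATF4 targets, which serve amino acid supply and 1-carbon metabolism, held 8 members that fell and 1 that rose of 34 (6 and 1 adjusted over the list alone). Aldh1l2 (-3.07 ± 0.40) and Cth (-1.89 ± 0.42) fell and the amino acid transporter gene Slc7a3 rose (0.99 ± 0.20), and the list gave a camera adjusted p of 0.00582 and adjusted p = 0.877 with an estimated correlation. Of 25 cholesterol synthesis genes 8 rose and 0 fell (9 and 1 adjusted over the list alone), among them Cyp51 (0.41 ± 0.07), Ebp (0.37 ± 0.07) and Nsdhl (0.48 ± 0.10). This list had a camera adjusted p of 0.0336, and adjusted p = 0.877 with an estimated correlation. Among 26 PBAF and BAF subunits 3 rose and 8 fell including Pbrm1 (3 and 10 adjusted over the list alone), with Bcl7a at 0.48 ± 0.05, Smarca2 at -0.53 ± 0.09 and Smarcc1 at -0.32 ± 0.06, and the list missed the camera threshold at an adjusted p of 0.106. Of 23 antioxidant enzyme genes 3 rose and 5 fell (3 and 5 adjusted over the list alone), with catalase, Cat, at 0.68 ± 0.11, Gpx8 at -2.24 ± 0.15 and Gpx1 at -0.74 ± 0.14; the list's median was 0.02 while its mean was -0.20 and camera pointed down at an adjusted p of 0.796.

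Knockdown under each stress asks whether the same genes depend on PBRM1 when cells are challenged. With H2O2, 3001 genes rose and 3236 fell, and in low glucose 2400 rose and 2745 fell (edgeR quasi-likelihood test, adjusted p under 0.05). Zdhhc15 fell furthest in both, by -6.79 ± 0.24 with H2O2 and -7.01 ± 0.25 in low glucose. Armcx4 fell in both as well (-3.88 ± 0.23 and -4.08 ± 0.22), and Sult1a1 rose in both (2.60 ± 0.44 and 3.29 ± 0.51). The thyroid hormone deiodinase gene Dio3 rose by 2.67 ± 0.32 with H2O2 and 2.46 ± 0.33 in low glucose. Cacna1e (3.72 ± 0.21), Pipox (2.37 ± 0.30), the potassium channel gene Kcnh7 (2.29 ± 0.33) and Cttnbp2 (2.30 ± 0.17) led the rises in low glucose, and Ugt2b36 (2.26 ± 0.31), Mal2 (2.24 ± 0.14) and Alpl, tissue-nonspecific alkaline phosphatase (2.13 ± 0.29), were among the leading rises with H2O2. The heparan sulfate proteoglycan Gpc1 (-3.72 ± 0.18) and the collagen receptor Ddr2 (-3.62 ± 0.47) fell with H2O2, and Cntln (-5.89 ± 0.28) and Ripor2 (-4.48 ± 0.34) in low glucose. Anxa13 with H2O2 (2.51 ± 0.57) and Atp6v1e1 (-6.39 ± 1.36) and Slc25a1 (-4.57 ± 0.72) in low glucose also passed, with SDs between replicates close to or above their means in at least 1 group for Anxa13 (7.14 ± 7.13 CPM) and Slc25a1 (7.31 ± 6.19 CPM). In all 3 conditions 3199 genes were called, 3196 of them in the same direction (1544 higher and 1652 lower). Across the 15169 genes, which are not independent replicates, the log2 changes correlated between conditions at Pearson r = 0.783, 0.778 and 0.785. These 3 comparisons share no library, but the labels do not say whether knockdown cells were made more than once. Any fixed difference between the knockdown and vector cells would recur in all 3, whether or not it came from PBRM1.

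With knockdown under stress, mesenchymal genes fell in 9 of 14 members with H2O2 and 10 of 14 in low glucose, with the same 9 and 10 adjusted over the list alone (camera adjusted p of 0.00495 and 0.000532, and adjusted p = 0.149 and 0.0981 with an estimated correlation). Basement membrane and integrin genes fell in 12 of 21 members in low glucose and rose in 1, with the same counts adjusted over the list alone (camera adjusted p of 0.000155, adjusted p = 0.371 with an estimated correlation); with H2O2 12 fell and 3 rose and camera missed the threshold at 0.0645. Chaperones and targets of ATF6 or XBP1 fell in 13 of 23 members in both stresses and rose in 1 with H2O2 and 2 in low glucose (14 fell in both adjusted over the list alone), with camera adjusted p of 0.00287 and 0.00246 (adjusted p = 0.601 and 0.580 with an estimated correlation). ATF4 targets fell in 24 of 34 members with H2O2 (24 adjusted over the list alone), at a median of -0.93. Camera gave this list 5.54e-05, and adjusted p = 0.877 with an estimated correlation. The median log2 level of the list was -0.976 in PBKD_H2O2 replicate 3 against -0.333 and -0.347 in replicates 1 and 2, and 0.262 to 0.578 in vector_H2O2 libraries. In low glucose 8 fell and 2 rose, and camera missed the threshold at 0.0655. Cholesterol synthesis genes rose in 12 of 25 members in low glucose and fell in 0 (12 and 0 adjusted over the list alone). Its camera adjusted p was 0.0096, and adjusted p = 0.877 with an estimated correlation. Averaged over the 3 conditions, 4222 genes were higher and 4472 lower in knockdown than in vector cells (edgeR quasi-likelihood test). These counts describe the difference between both kinds of cell, and how much of it came from PBRM1 was not tested. Zdhhc15 stood at -6.62 ± 0.13, Cntln at -5.12 ± 0.16 and Cacna1e at 3.54 ± 0.12. Slc25a11 (2.50 ± 0.85) was called in this average too, but fell to 1.21 without PBKD_H2O2 replicate 1 and also lost its call without PBKD_low_glucose replicate 2.

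The comparison of H2O2 with no stress in vector cells asks how cells with PBRM1 respond to oxidative stress. Targets of NRF2, the transcription factor of the antioxidant response, rose. Hmox1, heme oxygenase, went from 26.1 ± 1.99 to 156 ± 46.6 CPM (log2 2.58 ± 0.15), Osgin1 from 123 ± 4.21 to 307 ± 20.3 CPM (1.31 ± 0.08), Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, from 301 ± 6.09 to 704 ± 16.4 CPM (1.23 ± 0.05), and the sulfiredoxin gene Srxn1 rose by 0.92 ± 0.06. Of 25 NRF2 targets 11 rose and 0 fell (16 and 0 adjusted over the list alone). The camera adjusted p of 2.09e-10 held, with adjusted p = 0.00856 with an estimated correlation. The early response genes Egr1 (1.202 ± 0.17), Fos (0.75 ± 0.14), Dusp1 (0.62 ± 0.10) and Ier3 (0.59 ± 0.13) rose, among 6 of 26 immediate early genes that rose and 1 that fell (7 and 1 adjusted over the list alone), and that list missed the camera threshold at an adjusted p of 0.0922. Txnrd1, thioredoxin reductase, was the 1 of 23 antioxidant enzyme genes called (0.71 ± 0.13), against 5 adjusted over the list alone.

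Of 12 YAP/TAZ targets 6 rose and 0 fell with H2O2 in vector cells (8 and 0 adjusted over the list alone), among them Ankrd1 (0.55 ± 0.07), Ccn1 (0.72 ± 0.13), Amotl2 (0.43 ± 0.09) and Ccn2 (0.31 ± 0.07). In the camera test the adjusted p was 0.00031, and adjusted p = 0.535 with an estimated correlation. Of 22 lysosome and autophagy genes 7 rose and 0 fell (13 and 0 adjusted over the list alone), with Gabarapl1 at 0.48 ± 0.10 and Lamp2 at 0.24 ± 0.05. By camera the adjusted p was 7.74e-05, and adjusted p = 0.149 with an estimated correlation. Of 18 hypoxia targets 7 fell and 1 rose (9 and 1 adjusted over the list alone), among them Mxi1 (-0.57 ± 0.08), the prolyl hydroxylase subunit gene P4ha1 (-0.54 ± 0.08), Kdm3a (-0.44 ± 0.08) and Ankrd37 (-0.95 ± 0.17). The camera adjusted p was 0.00321, and adjusted p = 0.877 with an estimated correlation. Endoplasmic reticulum chaperones fell in 3 of 23 members and rose in 1 (5 and 1 adjusted over the list alone), with Pdia4 at -0.40 ± 0.06 and Hyou1 at -0.35 ± 0.07. This list had a camera adjusted p of 0.0163, and adjusted p = 0.709 with an estimated correlation. Cell cycle genes fell in 2 of 39 members (1 adjusted over the list alone), including the anaphase activator Cdc20 (-0.50 ± 0.10). Camera gave this list 0.0494, and adjusted p = 0.946 with an estimated correlation. In the inflammatory list Cxcl1 (0.66 ± 0.12), Tnfaip3 (0.56 ± 0.11) and 2 others of 21 rose and 0 fell (4 and 0 adjusted over the list alone), and camera missed the threshold at an adjusted p of 0.112.

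In vector cells 969 genes rose and 1051 fell with H2O2 (edgeR quasi-likelihood test, adjusted p under 0.05), 75 and 34 of them at least 2-fold. The total of 2020 came to 1025 without vector replicate 2, 1171 without vector replicate 3 and 1340 without vector_H2O2 replicate 1, and to 3513 without 5 libraries, the most distant of each group in which one lay more than 1.2 times the median distance away, a choice made after the data were seen. Several of the largest changes by size rested on few libraries. Ets2 (2.66 ± 0.72) lost its call without vector_H2O2 replicate 2, where it came to 0.19, and without any of the 3 vector libraries. Ptgs2, prostaglandin synthase (1.24 ± 0.31), lost its call without that same library, at 0.83, and without vector replicate 2. Uqcrc1 (-3.49 ± 1.10) came to -0.38 without vector replicate 1 and lost its call without each of the 3 vector_H2O2 libraries. Pfn1 (-2.09 ± 0.55) and Eif5a (-1.78 ± 0.50) came to -0.41 and -0.51 without vector replicate 3, and both also lost their calls without vector_H2O2 replicate 1, Eif5a further without vector_H2O2 replicate 2 or 3. Ripor2 (-1.04 ± 0.27, between -1.201 and -0.91) lost its call without vector replicate 2 or 3 or vector_H2O2 replicate 1 or 3, and Zfp428 (-0.98 ± 0.31, between -1.65 and -0.72) without any of these 6 libraries but vector_H2O2 replicate 3. Zfp428 was also among 30 genes that were higher in that library than in the rest of its group. Skiv2l (-3.34 ± 0.75) kept its call without each library.

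The same treatment in knockdown cells asks whether the response to H2O2 needs normal PBRM1 levels. NRF2 targets rose again, with Hmox1 at 2.15 ± 0.15 (18.5 ± 0.838 to 82.5 ± 10.6 CPM), Gclc at 1.59 ± 0.05 (259 ± 21.8 to 777 ± 4.72 CPM), Osgin1 at 1.07 ± 0.08 and Srxn1 at 1.03 ± 0.06. Of 25 members 15 rose and 0 fell (16 and 0 adjusted over the list alone), with a camera adjusted p of 4.7e-09 that held, at adjusted p = 0.00856 with an estimated correlation. The linker histone gene Hist1h1c (1.60 ± 0.17), Sipa1l2 (1.52 ± 0.08), the growth factor gene Fgf18 (1.46 ± 0.22) and the macrophage receptor gene Csf1r (1.62 ± 0.25, at 1.71 ± 0.635 and 5.34 ± 1.61 CPM) were the other large rises. The circadian repressor gene Ciart (-1.77 ± 0.33), the metalloprotease gene Adam12 (-1.23 ± 0.23) and the deoxycytidylate deaminase gene Dctd (-1.22 ± 0.26) fell. Cell cycle genes fell in 19 of 39 members and rose in 0 (27 and 0 adjusted over the list alone), among them the replication licensing genes Mcm4 (-0.59 ± 0.13), Mcm6 (-0.43 ± 0.11) and Mcm7 (-0.46 ± 0.11) and the mitotic kinase Plk1 (-0.49 ± 0.11). By camera the adjusted p was 9.73e-08, and adjusted p = 0.877 with an estimated correlation. The median log2 level of the list was 0.250, -0.0522 and 0.0099 in PBKD replicates 1 to 3, and -0.107, -0.168 and -0.568 with H2O2. ATF4 targets fell in 12 of 34 members and rose in 0 (17 and 0 adjusted over the list alone), including the lipoprotein receptor gene Vldlr (-0.37 ± 0.08). This list had a camera adjusted p of 0.000158, and adjusted p = 0.877 with an estimated correlation. Its median level was 0.327, -0.262 and 0.0076 in PBKD replicates 1 to 3, and -0.333, -0.347 and -0.976 with H2O2, so both lists were lowest in PBKD_H2O2 replicate 3 and, of unstressed knockdown libraries, highest in PBKD replicate 1. YAP/TAZ targets rose in 8 of 12 members (8 adjusted over the list alone), with Amotl2 at 0.59 ± 0.09, Ajuba at 0.37 ± 0.07 and Tgfb2 at 0.72 ± 0.15. Its camera adjusted p was 0.00287, and adjusted p = 0.66 with an estimated correlation. Lysosome and autophagy genes rose in 11 of 22 (11 adjusted over the list alone), with Lamp2 at 0.41 ± 0.05 and Map1lc3b at 0.39 ± 0.06. In the camera test the adjusted p was 4.1e-05, and adjusted p = 0.149 with an estimated correlation.

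In knockdown cells 1748 genes rose and 1813 fell with H2O2 (edgeR quasi-likelihood test), and the total of 3561 came to 2227 without PBKD replicate 1, 2035 without PBKD_H2O2 replicate 3 and 1695 where only the compared groups were fitted. Rnf181 (-3.31 ± 0.87) came to -0.33 without PBKD replicate 3, Etv4 (-1.43 ± 0.36) lost its call without PBKD replicate 1, and Cth (-1.51 ± 0.46, between -1.78 and -1.19) without PBKD replicate 1 or 3 or PBKD_H2O2 replicate 3. The interaction, which tests whether the response differed between knockdown and vector cells, called 0 genes by the edgeR quasi-likelihood test, with 1450 genes at an unadjusted p under 0.05 where 758 would be due to chance, and 31 genes by DESeq2. The count was 579 without the filter on low counts, 5 without the 5 libraries most distant within their groups, 4 without vector replicate 1, 1 without PBKD replicate 1 and 44 without vector_H2O2 replicate 3. Responses to H2O2 in the 2 kinds of cell correlated across genes at Pearson r = 0.403, and of 1310 genes called in both 2 went opposite ways. Median interaction values were -0.37 for ATF4 targets, -0.20 for NF-kB and inflammatory genes and -0.25 for cell cycle genes. These passed camera at adjusted p of 0.00619, 0.00287 and 2.42e-05, all lost at adjusted p = 0.877, 0.535 and 0.877 with an estimated correlation. Inflammatory genes had a median log2 level of 0.0013 in PBKD_H2O2 replicate 3 against 0.307 and 0.286 in replicates 1 and 2.

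Low glucose against no stress in vector cells asks how cells with PBRM1 respond to loss of their sugar source. Txnip and Arrdc4, arrestin-family genes driven by the glucose-sensing Mondo transcription factors, were among the largest falls, Txnip from 256 ± 12.3 to 5.21 ± 1.34 CPM (log2 -5.61 ± 0.17) and Arrdc4 from 31.9 ± 0.718 to 3.26 ± 0.208 CPM (-3.29 ± 0.10). The lipid droplet gene Plin4 (3.26 ± 0.32), the enolase gene Eno2 (2.42 ± 0.21), Lims2 (2.42 ± 0.17), Bnip3, a mediator of mitophagy (1.94 ± 0.24), and the serine protease gene Prss23 (1.85 ± 0.14) rose. Of 18 hypoxia targets 16 rose and 1 fell (16 and 1 adjusted over the list alone), with Ndrg1 at 1.53 ± 0.16, the collagen lysyl hydroxylase gene Plod2 at 1.31 ± 0.10, the oxygen sensor Egln1 at 1.15 ± 0.11 and Kdm3a at 0.81 ± 0.08, at a list median of 1.13. The camera adjusted p was 1.36e-13, and adjusted p = 0.149 with an estimated correlation. Of 16 glycolysis genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with the glucose transporter Slc2a1 at 1.06 ± 0.14, the hexokinases Hk2 and Hk1 at 1.23 ± 0.17 and 0.62 ± 0.11 and Tpi1 at 0.65 ± 0.11. Camera gave this list 2.03e-06, and adjusted p = 0.535 with an estimated correlation. Txnip and Arrdc4 were the 2 of 6 Mondo targets that fell (2 adjusted over the list alone), with a median of -0.13 and a mean of -1.53. By camera the adjusted p was 0.00278, and adjusted p = 0.0988 with an estimated correlation.

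Lysosome and autophagy genes rose in 15 of 22 members and fell in 1 (15 and 1 adjusted over the list alone) in low glucose. The folliculin complex genes Fnip1 (1.19 ± 0.06), Flcn (1.11 ± 0.07) and Fnip2 (0.71 ± 0.06), which control nutrient signalling at the lysosome, and the galactosidase gene Gla (0.72 ± 0.07) were among those that rose. This list had a camera adjusted p of 1.13e-08, and adjusted p = 0.0645 with an estimated correlation. Cholesterol synthesis genes rose in 9 of 25 members (10 adjusted over the list alone), with Insig1 at 0.70 ± 0.13 and Msmo1 at 0.35 ± 0.07. Its camera adjusted p was 0.00249, and adjusted p = 0.877 with an estimated correlation. Epithelial genes rose in 5 of 15 and fell in 1 (5 and 1 adjusted over the list alone), with Tjp1 at 0.35 ± 0.04 and Krt18 at 0.45 ± 0.07. In the camera test the adjusted p was 0.0163, and adjusted p = 0.827 with an estimated correlation. Heat shock genes fell in 5 of 16 (6 adjusted over the list alone), among them Stip1 (-0.35 ± 0.05), Fkbp4 (-0.32 ± 0.05) and Hsph1 (-0.29 ± 0.05). Its camera adjusted p was 0.0131, and adjusted p = 0.535 with an estimated correlation. Inflammatory genes fell in 6 of 21 and rose in 1 (8 and 1 adjusted over the list alone), with Nfkb2 at -0.32 ± 0.07. The camera adjusted p was 0.00846, and adjusted p = 0.62 with an estimated correlation. ATF4 targets fell in 5 of 34 and rose in 1, the 1 being Vldlr (0.63 ± 0.07; 5 and 1 adjusted over the list alone), while Ddit4 (-0.72 ± 0.16) and Sesn2 (-0.66 ± 0.16) fell. Camera gave this list 0.00246, and adjusted p = 0.877 with an estimated correlation. Its median level was -0.430 in vector_low_glucose replicate 1 against 0.187 and 0.458 in replicates 2 and 3. Chaperones of the endoplasmic reticulum fell in 6 of 23 and rose in 1 (9 and 1 adjusted over the list alone), with Syvn1 at -0.48 ± 0.07. By camera the adjusted p was 0.00754, and adjusted p = 0.66 with an estimated correlation. Of 27 nuclear genes of oxidative phosphorylation 7 fell and 0 rose (7 and 1 adjusted over the list alone), among them Cox5b (-1.21 ± 0.30) and Ndufb10 (-0.27 ± 0.06), and camera missed the threshold at an adjusted p of 0.499. Cox5b belonged to 30 genes at least 2-fold higher in vector_H2O2 replicate 3 than the mean log2 level of the other 2 libraries of its group. The median change of those genes in low glucose was -0.95 in vector and 0.16 in knockdown cells.

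In vector cells 1592 genes rose and 1343 fell in low glucose (edgeR quasi-likelihood test, adjusted p under 0.05), 164 and 96 of them at least 2-fold, and the total of 2935 came to 1816 without vector replicate 2 and 1934 without vector_low_glucose replicate 2. Atp6v1e1 (6.38 ± 1.37), Skiv2l (-3.70 ± 0.78) and Ier5l (-2.73 ± 0.64) kept their calls without each library, but Ier5l was, like Cox5b, among the 30 genes that set vector_H2O2 replicate 3 apart. Uqcrc1 (-4.07 ± 1.16) came to -0.96 without vector replicate 1 and lost its call without each vector_low_glucose library, and Pfn1 (-2.30 ± 0.56) came to -0.62 without vector replicate 3.

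In knockdown cells low glucose had its largest effects on many of the genes named for vector cells. Txnip fell from 319 ± 40.9 to 8.75 ± 0.539 CPM (-5.18 ± 0.17) and Arrdc4 from 28.5 ± 1.29 to 2.37 ± 0.0350 CPM (-3.59 ± 0.10), while Plin4 (3.23 ± 0.31), Eno2 (2.22 ± 0.21), Bnip3 (1.90 ± 0.24), Ankrd37 (1.61 ± 0.16) and the collagen prolyl hydroxylase subunit gene P4ha2 (1.60 ± 0.19) rose. Egr1 (-1.04 ± 0.18) and the transcription factor gene Pax9 (-1.01 ± 0.20) fell. Hypoxia targets rose in 16 of 18 members and fell in 0 (17 and 0 adjusted over the list alone), with Bhlhe40 at 1.49 ± 0.14 and Higd1a at 1.28 ± 0.13. This list had a camera adjusted p of 4.62e-20, and adjusted p = 0.0981 with an estimated correlation. Glycolysis genes rose in 13 of 16 (13 adjusted over the list alone), with Hk2 at 1.06 ± 0.17 and Slc2a1 at 0.80 ± 0.14. Its camera adjusted p was 1.03e-07, and adjusted p = 0.475 with an estimated correlation. Lysosome and autophagy genes rose in 15 of 22 and fell in 0 (15 and 1 adjusted over the list alone), with Fnip1 at 0.95 ± 0.06, Flcn at 1.04 ± 0.07 and Lamp2 at 0.47 ± 0.05, and this camera call held (adjusted p of 1.73e-12, and adjusted p = 0.0182 with an estimated correlation). Heat shock genes fell in 7 of 16 (9 adjusted over the list alone), with Hsph1 at -0.47 ± 0.05 (camera adjusted p of 3.44e-05, adjusted p = 0.0988 with an estimated correlation), and inflammatory genes in 5 of 21 (7 adjusted over the list alone), with Cxcl1 at -0.78 ± 0.11 and Ccl2 at -0.57 ± 0.11. In the camera test the adjusted p was 0.000371, and adjusted p = 0.371 with an estimated correlation. Cholesterol synthesis genes rose in 8 of 25 (12 adjusted over the list alone), with Insig1 at 0.68 ± 0.13. The camera adjusted p was 4.1e-05, and adjusted p = 0.877 with an estimated correlation.

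In knockdown cells 996 genes rose and 778 fell in low glucose (edgeR quasi-likelihood test), and the total of 1774 came to 1168 without PBKD replicate 3, 1073 without PBKD_low_glucose replicate 1 and 797 where only the compared groups were fitted. Oard1 (-4.22 ± 1.24) came to -1.05 without PBKD replicate 2 and lost its call without each PBKD_low_glucose library. Rnf181 (-3.49 ± 0.88) came to -0.50 without PBKD replicate 3 and also lost its call without each PBKD_low_glucose library, and Acadvl (2.64 ± 0.83, between 2.09 and 3.12) without 5 of the 6 libraries, all but PBKD_low_glucose replicate 1. The interaction called 1 gene, the imprinted zinc finger gene Peg3, by the edgeR quasi-likelihood test (-0.99 ± 0.13, adjusted p of 0.0097), with 651 genes at an unadjusted p under 0.05 where 758 would be due to chance, 6 genes by DESeq2 and 187 without the filter on low counts. Peg3 went from 54.8 ± 2.83 to 173 ± 17.4 CPM in vector cells and from 32.2 ± 3.66 to 51.4 ± 2.03 CPM in knockdown cells. Its interaction value stayed between -1.08 and -0.90 with any 1 library left out, and the call ended without vector replicate 1 or 2, PBKD replicate 2 or PBKD_low_glucose replicate 2 or 3. Responses to low glucose in the 2 kinds of cell correlated across genes at Pearson r = 0.435, and of 1370 genes called in both 1 went opposite ways.

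**Figure D2:**
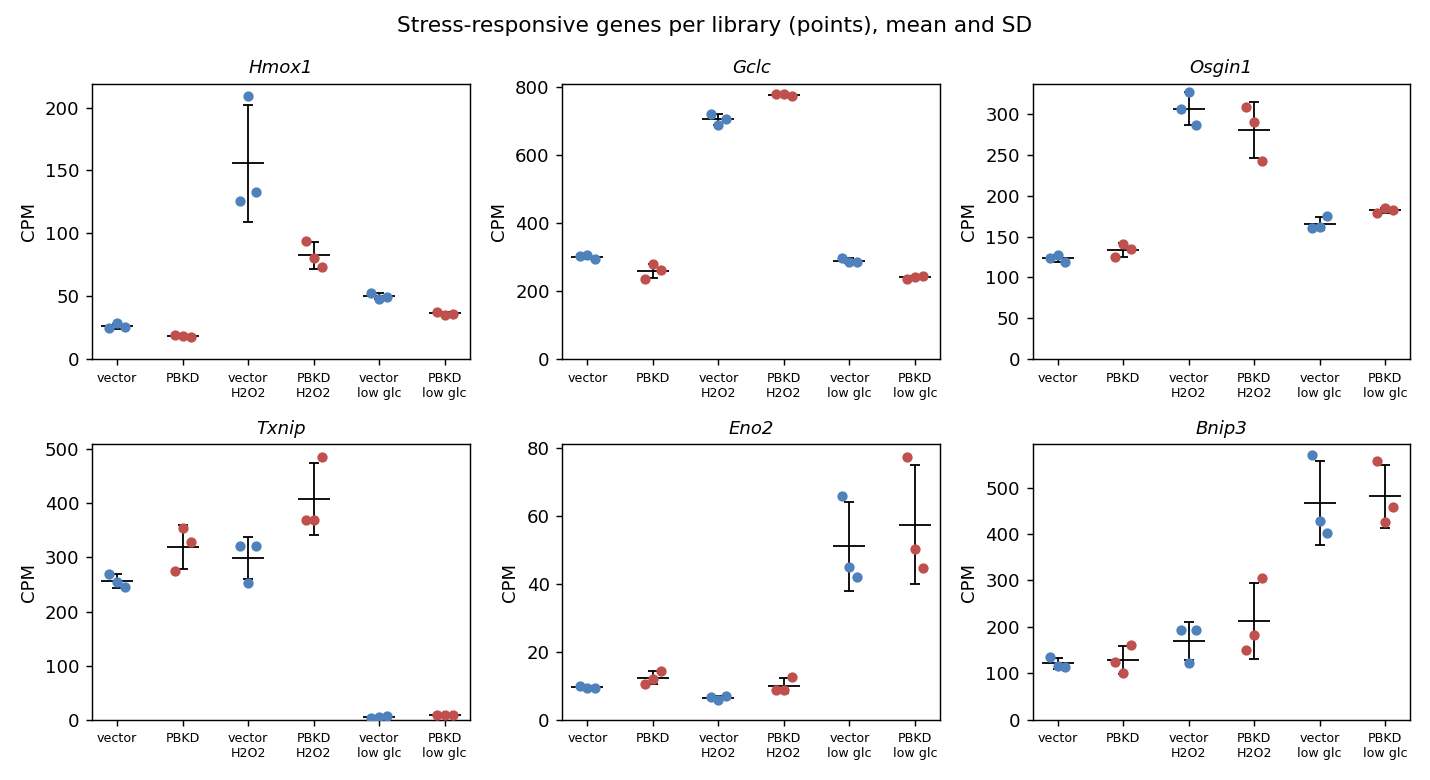
Hmox1, Gclc, Osgin1, Txnip, Eno2 and Bnip3 in CPM (vertical axes) in the 6 groups (horizontal axes). Points are libraries, black marks the mean and SD of 3 libraries, blue is vector and red is knockdown; Hmox1 rose with H2O2 to 156 CPM in vector and 82.5 CPM in knockdown cells, and Txnip fell in low glucose to 5.21 and 8.75 CPM.

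The responses of vector cells to H2O2 and to low glucose overlapped in 633 genes that went the same way. Of these 326 rose and 307 fell in both, where independent lists of these sizes would share 102 and 93.1, and 124 genes went opposite ways. Hmox1 rose in both stresses (2.58 ± 0.15 and 0.94 ± 0.15), as did Osgin1 (1.31 ± 0.08 and 0.43 ± 0.08) and Dusp1 (0.62 ± 0.10 and 0.65 ± 0.10). Kdm3a fell with H2O2 (-0.44 ± 0.08) and rose in low glucose (0.81 ± 0.08), as did Hk2 (-0.79 ± 0.18 and 1.23 ± 0.17), while Fos rose with H2O2 (0.75 ± 0.14) and fell in low glucose (-0.85 ± 0.15). The log2 changes correlated across genes at Pearson r = 0.366 with a covariance of 0.0576. In 20 simulations both stress groups were unchanged and shared 3 control libraries, which were simulated too. Through the shared controls alone these gave a mean r of 0.520 and a mean covariance of 0.0363, with 0 genes called in both. Each gene was drawn independently, so the simulations cannot show what deviations common to many genes in the real controls would give. The 3 control libraries could not be split, so part of the excess over independent lists may come from the shared controls. The overlap was 285 genes without vector replicate 2, 362 without vector replicate 3 and 405 without vector_H2O2 replicate 1, but 1170 without the 5 libraries most distant within their groups, and leaving out libraries was added for the overlap after the data were seen.

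**Figure D3:**
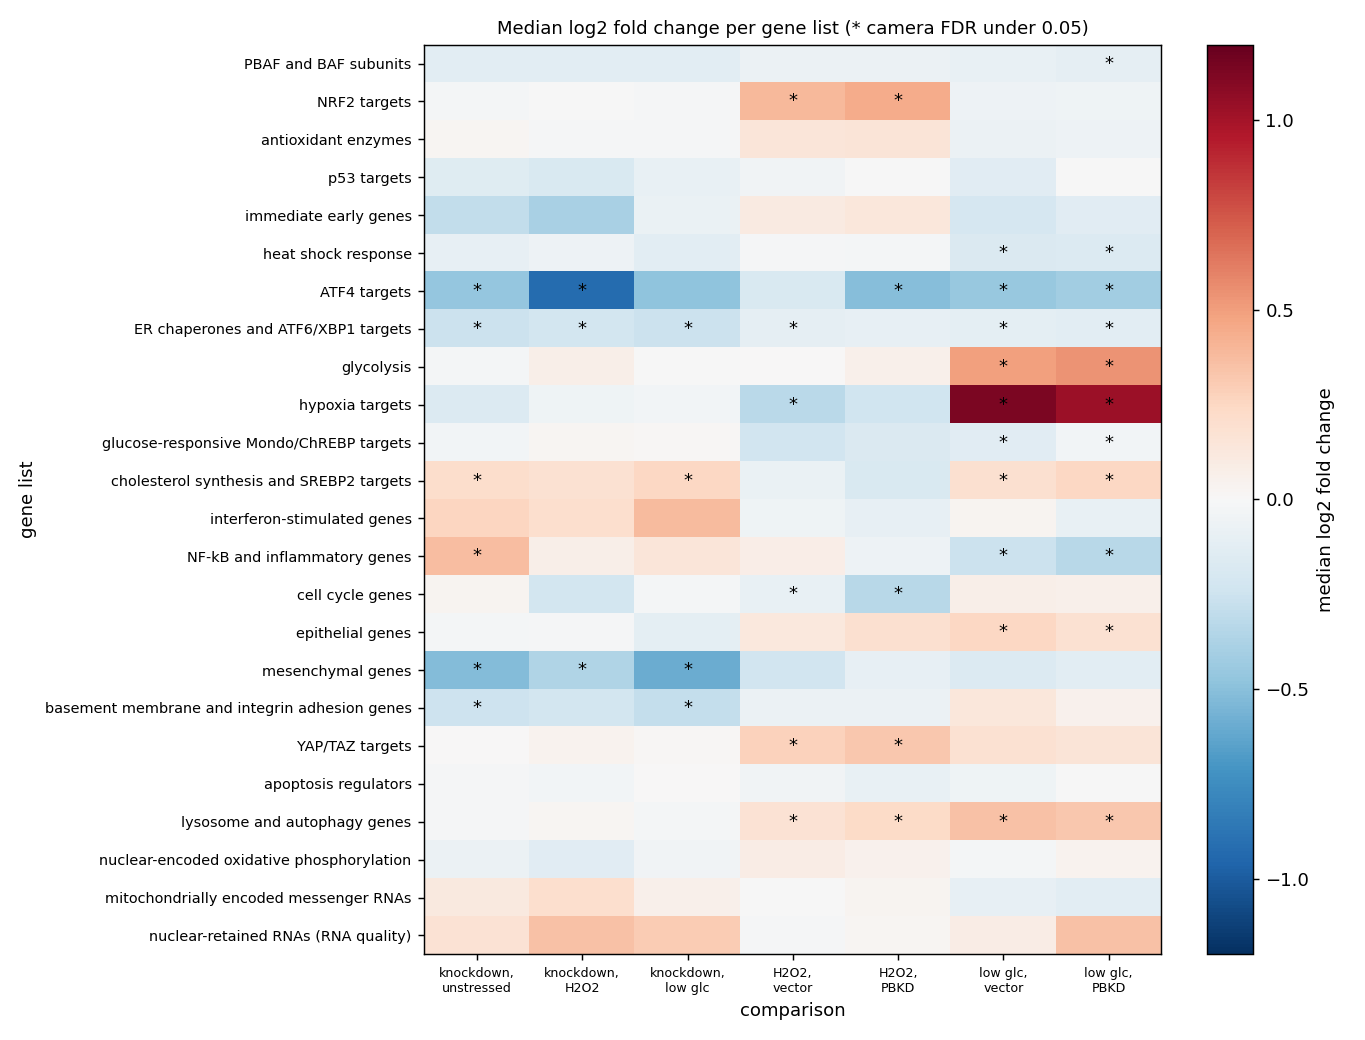
Median log2 fold change (colour) of the 24 gene lists (vertical axis) in 7 comparisons of 3 libraries against 3 (horizontal axis). Stars mark a camera adjusted p under 0.05 at the preset correlation; hypoxia targets in low glucose have the highest medians, at 1.13 in vector and 1.03 in knockdown cells.

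The region lists ask where chromatin opened or closed when PBRM1 was lowered. In NMuMG the deposited lists held 8136 regions of increased and 5245 of decreased accessibility, covering 9.52 and 4.82 Mb of mm10. Of the increased regions 17.01% and of the decreased 14.7% lay within 1000 bp of a transcription start, and most others were intronic (45.03% and 44.9%) or intergenic (30.6% and 34.6%). A region of increased accessibility lay over the promoter of Pbrm1 itself, on chromosome 14 from 31018901 to 31019499, with its centre 62 bp from the transcription start. The 3 widest decreased regions were on chromosome 8, over the promoter of the early response gene Ier2 (84658701 to 84667199) and in introns near Col4a2, a basement membrane collagen gene (11291701 to 11297099), and Ctu2 (122511001 to 122516399). The widest increased regions were intronic near Mroh2a on chromosome 1 (88225501 to 88266799) and 3632454L22Rik on X (135040501 to 135056699) and intergenic near Gm21119 on chromosome 8 (19697501 to 19711899). Decreased regions lay in the 5' UTR of Gclc (chromosome 9, 77754501 to 77755099) and at the promoter of Ciart (chromosome 3, 95881801 to 95883099). Increased regions lay at the promoters of Krt7 (chromosome 15, 101411201 to 101412099), Thbs1 (chromosome 2, 118111601 to 118112199) and Peg3 (chromosome 7, 6729401 to 6730299), in the 5' UTR of Col5a1 (chromosome 2, 27886101 to 27887099) and in an intron of Mal2 (chromosome 15, 54571901 to 54572699). Krt7 was also nearest to a decreased region, in an intron (101416201 to 101417199). Of these genes Gclc (-0.22 ± 0.05), Krt7, Thbs1, Col5a1 and Peg3 (-0.76 ± 0.09) had lower RNA in unstressed knockdown cells and Mal2 higher, and Ciart was not called. Of the 26 listed NRF2 targets 3 were nearest to increased regions alone and 10 to decreased regions alone (two-sided Fisher exact p of 0.00672), which missed the threshold at an adjusted p of 0.195 over the lists.

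Genes near increased regions were more often higher in RNA than genes near decreased regions, but this call was lost when chromosomes were taken into account. Of called genes nearest to increased regions alone 436 rose and 420 fell in unstressed knockdown cells (50.9% higher), and of those nearest to decreased regions alone 202 rose and 288 fell (41.2% higher), an odds ratio of 1.48 with a 95% interval of 1.18 to 1.85 (two-sided Fisher exact p of 0.000661; genes are not independent replicates). The call was kept within 5000 bp of a transcription start (odds ratio 1.55, p of 0.0034), with the average knockdown effect (1.31, p of 0.00155) and with the sign of all tested genes (1.16, p of 0.0322). It was lost at 1.34 for promoter regions alone (p of 0.219), 1.18 without chromosomes 12 and 13 (p of 0.186) and 1.13 when stratified by chromosome (Cochran-Mantel-Haenszel, p of 0.342), and the chromosome tests were chosen after the data were seen. Chromosome 12 genes had a median log2 knockdown change of 0.35 over the 3 conditions, with 93.0% of 329 genes above 0, and 91.1% of its changed regions were increased. Chromosome 13 genes had a median of -0.25, while 46.9% of its changed regions were increased. Chromosome 8, where 25.04% of changed regions were increased, had a median of -0.08, and chromosome 2, with 78.4% increased, a median of 0.02.

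**Figure D4:**
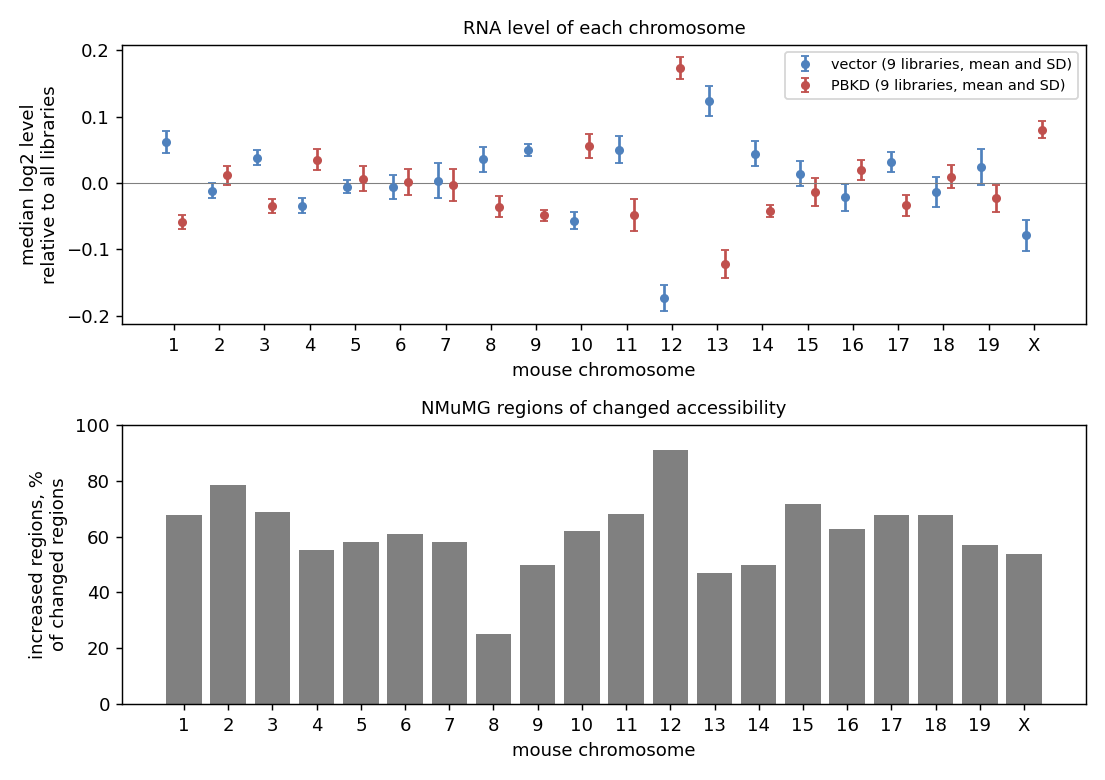
Upper panel, median log2 level of the genes of each mouse chromosome relative to all libraries, mean and SD of 9 vector (blue) and 9 knockdown (red) libraries; lower panel, percent of the changed NMuMG regions of each chromosome with increased accessibility. Chromosome 12 stands highest for knockdown and lowest for vector libraries in the upper panel; in the lower panel it stands highest, with 91.1% increased regions, and chromosome 8 lowest, with 25.04%.

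In HK-2 the deposited lists held 6751 regions of increased and 10785 of decreased accessibility, covering 9.22 and 13.4 Mb. Only 3.45% and 4.93% lay within 1000 bp of a transcription start as annotated by the authors, and 41.6% and 43.2% were intergenic. In the authors' deposited table fold changes, which for decreased regions were read from a column headed Peak Score, had a median of 1.79 in both lists and reached 7.64 among decreased and 22.7 among increased regions. By the authors' deposited table the decreased regions of highest fold were nearest BARX2 on chromosome 11 (129309901 to 129310599, 7.64), MIR1207 on 8 (128093101 to 128093399, 7.19) and LINC02120 on 5 (32852501 to 32852899, 6.57), and high-fold increased regions were nearest PRAME on 22 (22596401 to 22598199, 11.4) and PLEKHA6 on 1 (204307501 to 204308199, 10.8). Sources for these lists name different genome builds, hg38 in the file headers and hg19 in the submitters' processing notes, so the nearest genes in HK-2 are uncertain.

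The 2 cell lines were compared over 1520 genes of the same symbol that were nearest to regions of 1 direction in each. Of genes near increased HK-2 regions 315 were near increased and 152 near decreased NMuMG regions (67.5% increased), and of those near decreased HK-2 regions 631 and 422 (59.9% increased), an odds ratio of 1.39 with a 95% interval of 1.10 to 1.74 (two-sided Fisher exact p of 0.00588). With regions within 5000 bp of a transcription start the odds ratio turned to 0.861 (366 genes, p of 0.513), and with promoter regions alone it was 1.57 (28 genes, p of 0.698). Both the odds ratio and its alternatives rest on the HK-2 nearest genes, whose build is uncertain.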

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

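Tests of chromosome 12, of the genes that set an H2O2 library apart and of HK-2 genome builds were chosen after the results were seen; only the splits of libraries and the test of gene density were planned before.

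Peg3 differed between groups, with a low glucose response lower in knockdown than in vector cells by an interaction value of -0.99 ± 0.13 (edgeR quasi-likelihood test, adjusted p of 0.0097). The call ended without vector replicate 1 (-0.95) or 2 (-0.98), PBKD replicate 2 (-0.94) or PBKD_low_glucose replicate 2 (-0.97) or 3 (-0.98). Of 100 splits of the libraries 9 called as many genes as the 1 found, and the highest count in a split was 2796. Splits redrew the knockdown and vector labels separately in each condition. A split can thus turn the knockdown difference itself into an interaction. The splits therefore cannot decide on chance for this count, and chance is not excluded. Which split gave 2796 was not examined. The H2O2 response differed between knockdown and vector cells in ATF4 targets (median interaction -0.37), NF-kB and inflammatory genes (-0.20) and cell cycle genes (-0.25). Their camera adjusted p were 0.00619, 0.00287 and 2.42e-05, and adjusted p = 0.877, 0.535 and 0.877 with an estimated correlation. ATF4 and cell cycle levels stood out in PBKD replicate 1 (0.327 and 0.250) and PBKD_H2O2 replicate 3 (-0.976 and -0.568). The inflammatory level stood out in PBKD_H2O2 replicate 3 too, at 0.0013 against 0.307 and 0.286 in replicates 1 and 2. The low glucose response differed in basement membrane and integrin genes (-0.10, camera adjusted p of 0.0022, adjusted p = 0.535 with an estimated correlation) and in nuclear genes of oxidative phosphorylation (0.0593, camera adjusted p of 0.0152, adjusted p = 0.877 with an estimated correlation). The 30 genes higher in vector_H2O2 replicate 3, of which Cox5b alone belongs to that list, had medians of -0.95 in vector and 0.159 in knockdown cells in low glucose, so they moved the same way as that list. In the H2O2 interaction 0 genes were called by edgeR, with 1450 at an unadjusted p under 0.05, and 31 by DESeq2. All 100 splits called as many by construction, so the splits say nothing on chance there. At most 5486 genes were called in a split. Exchanging knockdown and vector labels in 1 condition makes the interaction the sum of 2 knockdown differences, so high counts can arise by construction. Which split gave 5486 was not examined.

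For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. In each of these the real split alone, 1 of 10, called as many genes as observed. Real and highest other counts were 4794 and 0 for unstressed knockdown, 6237 and 0 for knockdown with H2O2, 5145 and 0 in low glucose, 2020 and 0 for H2O2 and 2935 and 0 for low glucose in vector cells, and 3561 and 4 for H2O2 and 1774 and 0 for low glucose in knockdown cells. The average knockdown effect called 8694 genes against at most 7262 in another of 100 splits, 1 of 100 reaching the real count. That goes against a chance division of these libraries. It cannot exclude chance differences between cultures, as the labels do not say whether knockdown cells were made more than once. The split that called 7262 exchanged whole groups within a condition and so holds part of the knockdown difference.

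Genes of chromosome 12 were higher in the knockdown libraries in each condition. A few strongly changed genes are excluded as the cause, since genes changed less than 2-fold differed from those of other chromosomes by a median of 0.373, or 1.29-fold. In level 9 of 9 knockdown libraries lay above every vector library (exact permutation p of 4.11e-05, the smallest 9 against 9 can give). That goes against variation from library to library. Variation between cultures is not excluded, since the labels do not say whether knockdown cells were made more than once. Of 20 chromosomes 12 were parted as fully, up or down, so the separation is not particular to chromosome 12. The hypothesis of more copies of chromosome 12 in the knockdown culture could account for this, as 91.1% of its changed regions were increased, against at most 78.4% on another chromosome, and 11 of 11 windows had a median above 0.1. Regional control of the chromosome by PBRM1 could give the same values, and no DNA was counted to tell these apart.

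The genes that set vector_H2O2 replicate 3 apart were 32, of which 30 were higher. The median log2 level of the 30 was 0.760 in that library, and -0.514 and -0.643 in replicates 1 and 2. Unstressed vector libraries had 0.704, 0.638 and 0.492, so replicate 3 stood near unstressed cells and replicates 1 and 2 lower. With H2O2 the 30 had a median change of -0.57 in vector and 0.35 in knockdown cells. Among these 30 genes were Cox5b, Cox6a1, Cox8a, Chchd2, Romo1, Jun and Cebpb. A difference in library preparation could account for them, since in knockdown cells the same genes differed by a median of -0.814 between low glucose replicate 1 and replicates 2 and 3, where other genes differed by -0.00702. A response to low glucose stays open, as their median in low glucose was -0.95 in vector cells and 0.159 in knockdown cells, where library levels spread too widely to decide (-0.668, 0.158 and 0.255 against -0.0014, -0.182 and -0.411 without stress). Without them 2022 genes were called for H2O2 and 2918 for low glucose in vector cells.

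HK-2 regions near transcription starts were concentrated in few windows, with 41.2% of them in the 26 of 253 windows with the highest shares, against 11.5% in 16 of 152 windows in NMuMG. That difference of 29.7 percentage points met the prediction against gene density, but cannot exclude it. HK-2 had fewer regions near starts, 532 decreased and 233 increased against 773 and 1384 in NMuMG, spread over more windows. Gene density itself was not measured in either genome. Coordinates of 1 build annotated with another were tested by the ratio of shares near a start inside and outside segments where hg19 and hg38 nearly coincide, taken approximately from general knowledge. The joint test failed at a ratio of 1.25, and after it failed the lists were split: 12.98 for decreased regions (45.6% of 364 against 3.51%) and 1.25 for increased regions (4.30% of 93 against 3.44%), which goes against this cause. A mismatch in the decreased list alone may hold but stays open, since the split that gave 12.98 was made after the joint test failed.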

How the results depend on the processing

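With the replicate block, DESeq2 size factors, 5 mean CPM and 2 surrogate variables (the last added after the data were seen), counts of the 7 comparisons of 3 with 3 libraries and of the average moved by less than 1.5 times. With DESeq2 the interactions called 31 genes for H2O2 and 6 for low glucose, and without a filter 579 and 187. With only the compared groups, H2O2 and low glucose in knockdown cells called 1695 and 797 genes and the low glucose interaction 3. Without 5 libraries, each the most distant of its group, added after the data were seen, H2O2 in vector cells called 3513 genes, the interactions 5 and 4, and the overlap of both stresses was 1170. For these changes the cause was not tested. A 2-fold threshold left by construction 898, 1127, 965 and 1025 genes for knockdown unstressed, with H2O2, in low glucose and on average, 109 and 260 for H2O2 and low glucose in vector and 239 and 126 in knockdown cells, 0 for the low glucose interaction (651 at an unadjusted p under 0.05, edgeR) and 23 in the overlap. Correlations of knockdown effects between conditions lay between 0.712 and 0.813 with the block, with genes of at least 5 mean CPM and without those 5 libraries.

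Leaving out each library in turn gave 3379 to 5343 genes for unstressed knockdown, 4693 to 5945 with H2O2, 4017 to 4749 in low glucose and 8236 to 8985 on average. It gave 1025 (without vector replicate 2) to 1761 for H2O2 and 1816 to 2266 for low glucose in vector cells, and 2035 (without PBKD_H2O2 replicate 3) to 3764 and 1073 (without PBKD_low_glucose replicate 1) to 1771 in knockdown cells. The H2O2 interaction called 0 to 44 genes, 44 without vector_H2O2 replicate 3, 4 without vector replicate 1 and 1 without PBKD replicate 1. The low glucose interaction called 0 to 2, with 2 without PBKD replicate 1 or 3 or vector_low_glucose replicate 1 and 0 without vector replicate 1 or 2, PBKD replicate 2 or PBKD_low_glucose replicate 2 or 3. The overlap was 285 (without vector replicate 2), 362 (vector replicate 3), 405 (vector_H2O2 replicate 1) and up to 706, and leaving out libraries was added for it after the data were seen. Fewer libraries were tested in each, and no other cause was tested. Of 769 called results of named genes 608 kept their call under every alternative chosen beforehand but the fold threshold, 161 lost it in at least 1, 137 of them when a library was left out, and 0 turned direction.

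Same-numbered libraries correlated between -0.614 and 0.630, 13 of 45 pairs above 0.1, and 8 of 18 libraries correlated best with their own number, a hint from the data and not the design. With the replicate block counts were 4635, 6121, 4978 and 8598 for knockdown, 1835 and 2731 for the stresses in vector and 3429 and 1618 in knockdown cells, 0 and 2 for the interactions and 546 for the overlap. In the knockdown comparison in low glucose, where pairs were taken from the data, Ndufb10 was the 1 named gene to lose its call with the block. Of 55 list calls an estimated correlation kept 3 and ended 52, fry ended 15 and added 42, and the replicate block ended 0 and added 1, cell cycle genes in knockdown with H2O2 (adjusted p of 0.0446).

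Regions above the median fold or width numbered by construction 5386 and 3373 in HK-2 and 2144 and 3943 in NMuMG, decreased and increased. The odds ratio of accessibility and RNA was 1.55 within 5000 bp, 1.31 with the average knockdown effect and 1.16 with the sign of all tested genes, each still called. It was 1.34 with promoter regions, and 1.18 without chromosomes 12 and 13 and 1.13 by chromosome, both added after the data were seen, and the call was lost in these 3. That of HK-2 and NMuMG turned to 0.861 within 5000 bp and was 1.57 with promoter regions; the cause was not tested. In HK-2 windows with a high share near starts, 1 gene was near increased regions, so no odds ratio could be had.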

Other observations

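Interferon-stimulated genes moved both ways in unstressed knockdown cells, where 9 of 27 rose and 3 fell (9 and 3 adjusted over the list alone), at a camera adjusted p of 0.106. The viral RNA sensors Ifih1 (1.23 ± 0.14) and Ddx58 (0.46 ± 0.09) and the chemokine Cxcl10 (2.44 ± 0.41) rose, while the mitochondrial nucleotide kinase Cmpk2 fell (-2.38 ± 0.33). Of 25 p53 targets 2 rose and 5 fell (2 and 5 adjusted over the list alone), with Perp (-0.85 ± 0.08), Phlda3 (-0.48 ± 0.09) and Mdm2 (-0.37 ± 0.07) among those that fell, at a camera adjusted p of 0.14. Of 26 immediate early genes 2 rose and 7 fell (3 and 9 adjusted over the list alone), with Gadd45b at 0.68 ± 0.13, Klf6 at -0.44 ± 0.10 and Atf3 at -1.03 ± 0.23. Of 25 NRF2 targets 4 rose and 6 fell (4 and 6 adjusted over the list alone), with the glutathione transferase genes Gstm1 (0.95 ± 0.14) and Gsta4 (0.71 ± 0.11) higher and Sqstm1 (-0.70 ± 0.13) lower. YAP/TAZ targets split 5 to 3 of 12 (5 and 3 adjusted over the list alone), with Nt5e at -1.88 ± 0.22 and Ankrd1 at 0.37 ± 0.07, and lysosome genes 5 to 4 of 22 (5 and 4 adjusted over the list alone), with the cathepsin gene Ctsl at -0.92 ± 0.11 and the nutrient-sensing GTPase gene Rragd at 2.67 ± 0.40. Medians, means and camera differed in sign for YAP/TAZ targets (0.00, -0.07, up), lysosome genes (-0.01, 0.06, down) and Mondo targets (-0.03, -0.00350, up). The apoptosis activator Hrk fell (-4.94 ± 0.69) among 21 apoptosis regulators, 3 of which rose and 2 fell (0 and 2 adjusted over the list alone). Of 13 mitochondrially encoded messenger RNAs 5 rose and 0 fell (5 and 0 adjusted over the list alone), among them mt-Nd2 (0.34 ± 0.06), and of 27 nuclear genes of oxidative phosphorylation 0 rose and 7 fell (0 and 7 adjusted over the list alone), among them Atp5b (-0.28 ± 0.06). The 30 genes higher in vector_H2O2 replicate 3, Cox5b among them, had a median of -0.76 in this comparison. Heat shock genes split 3 to 3 of 16 (3 and 4 adjusted over the list alone), hypoxia targets 2 to 5 of 18 with Vegfa at -0.42 ± 0.07 (2 and 5 adjusted over the list alone), and cell cycle genes 3 to 1 of 39 (2 and 0 adjusted over the list alone). Glycolysis genes fell in 2 of 16 (2 adjusted over the list alone), with Pkm at -0.26 ± 0.08, and among 6 Mondo targets Pklr rose (0.52 ± 0.08; 1 adjusted over the list alone).

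Most markers of other cell types were low in these cultures, with Mylk the exception at 61.9 CPM in vector and 93.9 CPM in knockdown cells in unscaled counts. The milk protein gene Csn3 fell from 7.94 to 1.40 CPM in unstressed knockdown cells (-2.54 ± 0.29), while Mylk, a contractile kinase gene listed as a basal marker, rose (0.58 ± 0.10), and the macrophage marker Cd68 rose (0.69 ± 0.15) from 2.36 to 3.85 CPM. Of 3 tested basal markers 1 rose and 0 fell (1 and 0 adjusted over the list alone; median -0.37 while camera pointed up), and of 4 immune markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.14, mean -0.21, camera up). Ptprc, a marker of blood cells, stood at 0.501 and 0.483 CPM in unscaled counts, and of 3 endothelial markers 0 rose and 1 fell (1 and 1 adjusted over the list alone). The nuclear-retained RNA Malat1, read as a sign of RNA quality, was at 0.50 ± 0.19 in unstressed knockdown against vector cells, and of 3 such RNAs 0 were called by the edgeR quasi-likelihood test (1 adjusted over the list alone) at a camera adjusted p of 0.67. Within knockdown cells, low glucose against no stress lowered chaperones of the endoplasmic reticulum (7 of 23 fell, 7 adjusted over the list alone), with Hyou1 at -0.40 ± 0.07. That list had a camera adjusted p of 0.0096, and adjusted p = 0.687 with an estimated correlation. In that comparison PBAF and BAF subunits fell in 4 of 26 and rose in 2 (8 and 2 adjusted over the list alone), at a camera adjusted p of 0.0431 and adjusted p = 0.601 with an estimated correlation. There epithelial genes rose in 2 of 15 (2 adjusted over the list alone), with Tjp1 at 0.21 ± 0.04, at a camera adjusted p of 0.0446 and adjusted p = 0.877 with an estimated correlation. ATF4 targets there had a median of -0.42, with 1 rise, Vldlr (0.60 ± 0.07; 1 adjusted over the list alone), at a camera adjusted p of 0.0143 and adjusted p = 0.877 with an estimated correlation. Their median level was -0.980 in PBKD_low_glucose replicate 1 against -0.182 and -0.0539 in replicates 2 and 3. Mondo targets held 2 falls of 6, Txnip and Arrdc4 (2 adjusted over the list alone), at a camera adjusted p of 0.00643 and adjusted p = 0.129 with an estimated correlation.

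Chromosome 13 genes were lower in knockdown libraries, with a median of -0.25 over the conditions and 10 of 12 windows under -0.1, and X genes were higher at a median of 0.15. Chromosome 12 and 13 together held 588 (9.87%) of the 5957 genes called on average among 9327 genes with a chromosome and a mean log2 CPM above 3. Of those 9327 genes, called or not, 329 lay on chromosome 12 and 356 on chromosome 13. Over 217 windows the median RNA change and the percent of increased regions had a Spearman rho of 0.0320.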
